A study of Rattus norvegicus with 12 samples.

How the data were processed

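The data are 12 arrays of total RNA from primary adult rat ventricular cardiocytes in serum-free culture, 6 of control cells and 6 of cells given neuregulin-1 beta for 24 hours, per the labels. Each array's group and number were taken from its title. The deposited table holds 1 intensity per probe and array for 1185 probes. The array design, the labelling, the scanner, any background subtraction and any normalisation are not given in the sources used here. The deposited intensities are whole numbers on a linear scale with 0 missing values and none at or below 0. Array totals run from 3496129 to 30450581, so the values were taken as not normalised between arrays. The lowest value on any array is 990, so the values were taken to include background. No 2 arrays held identical values.

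Gene names were sought by setting the probe codes against the identifiers, symbols and synonyms of the rat gene table of assembly GRCr8. Of 1185 codes, 1 coincided with a synonym, which was not taken as a match. The probes therefore stay unnamed, control spots could not be told from others and were not removed, and the gene lists, cell type markers and fixed genes chosen beforehand were not tested. The rule for naming single results, written before the data were examined, allowed at most 2 probes that rose and 2 that fell where codes have no gene names. Because no probe passed the threshold, the 2 of smallest unadjusted p in each direction are given and are said not to pass.

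Values were put on the log2 scale without an offset. Array medians differed by more than 0.2 on that scale, so quantile normalisation was applied, as set down beforehand. Each probe was tested with limma (lmFit and eBayes, version 3.58.1, in R 4.3.3) for neuregulin against control over all 12 arrays with no covariate, two-sided, with Benjamini-Hochberg adjustment over the 1185 probes and a threshold of 0.05. Quantile normalisation gives every array the same distribution, so a change in the overall level of RNA cannot be seen after it, and the brightest probes can take only a few values. Fold changes are on the scale of the normalised intensity, background included, which understates changes of dim probes.

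The test was checked on simulated data drawn with each probe's own mean and spread in these arrays. When 200 of the 1185 probes were changed by 0.5 on the log2 scale, 85.0% were called, with 10 false calls. At 1 it was 97.5% with 8 false calls, and at 2 it was 100% with 7. With no change there were 0 calls. The share depends on how many probes change: with 10 changed probes per draw, over 20 draws, 64.5% were called at 0.5, 90.5% at 1 and 96.5% at 2. These simulations draw normal noise per probe, independent between probes, and so leave out the shared structure of the arrays. The changes were added to the normalised values, background included, with no further normalisation. For probes near the floor they stand for larger changes in transcript abundance, so the shares called do not hold for transcript changes of the stated size. The shares were not split by brightness, and 866 of the 1185 probes did not pass 2 times the array median on any array. The confidence interval of the measured log2 change reached 0.19 to either side at the median over all probes. Among the 119 probes of highest mean intensity it reached 0.47 at the median. The shares called at 0.5 therefore cannot be taken to hold for those 119 probes.

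Array quality was described by the median, the 5th, 95th and 99th percentiles, the number of probes above 2 times the array median, and Spearman correlations between arrays across probes. These are technical measures, chosen after the data were examined, as were the signal classes. An array is called bright where its 99th percentile is above 100000. The other arrays are of the high floor class where the 5th percentile is above 2000, and of the low floor class otherwise. Single array measures and principal components were compared between groups by exact permutation over all 924 splits of the 12 arrays, which allow a smallest two-sided p of 0.00216.

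Alternatives fixed beforehand were the deposited values without normalisation, median centring, removal of the 25% of probes with the lowest mean, an offset of 1445 (the 10th percentile of all values) before log2, the replicate number as a block, array weights, trended and robust moderation, an exact permutation test per probe, an adjusted threshold of 0.10, and leaving out each array in turn. Normexp background correction with an offset of 50, cyclic loess, the signal class as a block or fitted alone, a filter to the 179 probes above 2 times the median on at least 3 arrays of a group, and removal of the arrays with little signal over the floor were added after the data were examined. Whether the numbers 1 to 6 pair the arrays was checked from the correlation of same-numbered arrays' deviations from their group means. It was not over 0.1 for every number. The main model had been fixed beforehand without the block, because the titles do not say that the numbers mark shared cultures, and it was kept. Figures were drawn with matplotlib 3.10.9.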

Results

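Primary heart muscle cells (cardiocytes) from the ventricles of adult rats were kept in serum-free culture and either left without the factor or exposed to neuregulin-1 beta for 24 hours. Neuregulin-1 beta is a growth factor of the epidermal growth factor family that acts on heart muscle cells through the ErbB receptors. The design asks which transcripts differ in abundance between stimulated and unstimulated cells. Total RNA was profiled on 12 arrays, 6 of control cells and 6 of stimulated cells, with 1 intensity for each of 1185 probes on every array. The labels number the arrays 1 to 6 in each group and do not say which arrays came from separate animals or cultures. The p-values below therefore measure the spread between these arrays, part of which may be technical.

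The probes carry codes of the array's design, and no table used here pairs the codes with genes. Probes are therefore named by their codes, and no gene, chromosome position or transcript region can be given for them. For the same reason the 22 lists of genes and the 5 lists of cell type markers that were drawn up for heart muscle cells before the data were examined could not be tested. They included the ErbB receptors, the phosphoinositide 3-kinase pathway, regulators of apoptosis, respiratory chain subunits and sarcomere proteins. No statement on any of these groups, or on other cell types in the cultures, is made here.

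The arrays differed in brightness far more than the groups did. Median intensities per array ran from 1611 to 5603 in the control group and from 1540 to 5079 in the neuregulin group. The mean over control arrays was 3288 ± 1836 (SD, n = 6), against 2644 ± 1404 (SD, n = 6) over neuregulin arrays. On the log2 scale the medians were 0.28 lower with neuregulin, a difference smaller than the spread between arrays (exact permutation test over 924 splits, two-sided, p = 0.530, adjusted p = 0.771 over 3 array measures). The lowest value on an array was never under 990, and it reached 3371 on control array 3.

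Few probes stood well above the median of their own array, which was used here in place of a measured background. The number of probes above 2 times the array's own median was 148 ± 86.7 (SD, n = 6) on control arrays and 164 ± 74.0 (SD, n = 6) on neuregulin arrays (exact permutation test, two-sided, p = 0.727, adjusted p = 0.771). Of the 1185 probes, 866 did not pass that level on any array and 39 passed it on all 12. It was passed by 263 probes on control array 3 and by 277 on neuregulin array 3. Control array 2 had 50 such probes and neuregulin array 2 had 56. On control array 3 the median was 5603 against a lowest value of 3371, so this level can miss probes that lie above the floor. For most probes closeness to the floor limits what can be measured.

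**Figure D1:**
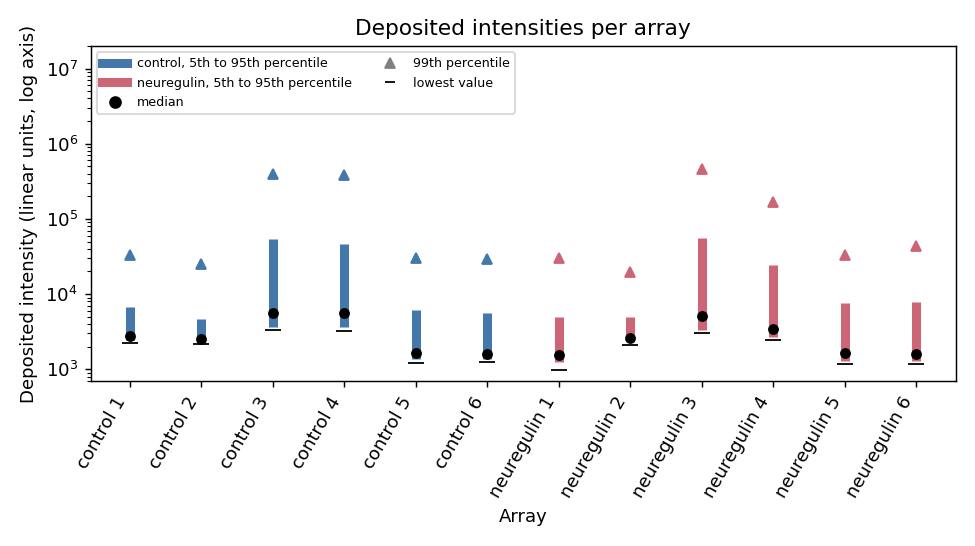
Deposited intensity (linear units on a log axis) for each of the 12 arrays. Bars run from the 5th to the 95th percentile over probes, circles mark the median, triangles the 99th percentile and dashes the lowest value. Arrays 3 and 4 of both groups reach 99th percentiles of 169061 to 467442, while the other 8 arrays stay between 19728 and 43514.

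By these values the arrays fell into 3 signal classes, each with arrays of both groups. Control arrays 3 and 4 and neuregulin arrays 3 and 4 were bright, with 99th percentiles above 100000. Control arrays 1 and 2 and neuregulin array 2 combined dim signals with a high floor, their 5th percentiles lying between 2297 and 2489. Control arrays 5 and 6 and neuregulin arrays 1, 5 and 6 combined dim signals with a low floor, with 5th percentiles between 1244 and 1382. The 95th percentile was only 1.84 to 2.38 times the median on the 3 arrays of the high floor class, against 7.27 to 11.0 times on the bright arrays.

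Arrays of the same treatment did not resemble each other more than arrays of different treatments. Across probes, the mean Spearman correlation was 0.773 over the 30 pairs of arrays within a group and 0.779 over the 36 pairs between groups. The difference of -0.0059 was not above that of other splits of the 12 arrays (exact permutation test over 924 splits, one-sided, p = 0.574). These splits do not hold the signal classes fixed, and no relabelling within classes was run for this measure. The most similar pair was control 3 and neuregulin 3 (rho = 0.960), and the least similar was control 1 and neuregulin 1 (rho = 0.576). Pairs within a signal class had a mean rho of 0.845 (19 pairs), against 0.749 over the 47 pairs from different classes. Within the bright class the mean was 0.935 over 6 pairs, within the low floor class 0.822 over 10 and within the high floor class 0.743 over 3. The gap rests largely on the 3 high floor arrays, whose mean rho with all others was 0.678 to 0.682. The other 9 arrays, bright and low floor together, had a median rho of 0.875 among themselves. Probes are not independent replicates, so these correlations describe the arrays only.

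**Figure D2:**
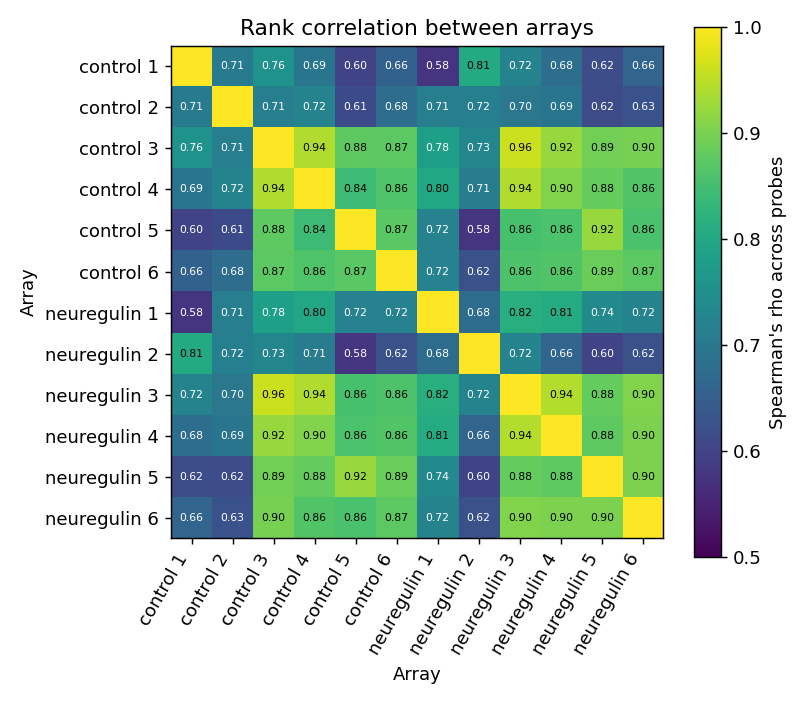
Spearman correlation of deposited intensities across the 1185 probes for each pair of arrays, with controls first and neuregulin arrays after them. Values run from 0.576 to 0.960, and the rows of control 1, control 2 and neuregulin 2 are the lowest, with mean rho of 0.680, 0.682 and 0.678.

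After quantile normalisation, the first principal component carried 38.2% of the variance between arrays. The groups' difference on it was within the spread between arrays (exact permutation test, two-sided, p = 0.950, adjusted p = 0.950 over 3 components). Arrays 5 and 6 of both groups lay at 4.72 to 6.32 on this component, and control 2 and neuregulin 2 at -8.46 and -7.02. Control 1 lay at -1.23 and neuregulin 1 at -6.92. The next components carried 15.8% and 13.4%, with differences that were also within the spread (exact permutation tests, two-sided, p = 0.476 and p = 0.305, adjusted p = 0.714 for both).

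No probe passed the threshold for a change with neuregulin. Of the 1185 probes tested, 0 were higher and 0 were lower at an adjusted p under 0.05 (limma, Benjamini-Hochberg adjustment, two-sided), and the smallest adjusted p was 0.125. The exact permutation test per probe cannot give a p under 0.00216, which needs complete separation of the groups. At least 52 probes at that p, or more at a larger p, would be needed before any passed adjustment. Only 3 probes separated the groups completely, and the permutation test's count of 0 (smallest adjusted p 0.570) is no separate evidence. An unadjusted p under 0.05 was reached by 59 probes with limma, 31 higher and 28 lower, where chance alone gives 59.3 on average. The count varied widely between other splits of the same 12 arrays, up to 300, so its closeness to 59.3 is no evidence that nothing changed. With the exact permutation test 63 probes reached it. The limma count moved with the model and the scaling. It was 102 with array weights, 93 with the replicate number as a block and 92 with the signal class as a block. With median centring it was 16, and without normalisation 0.

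With background left in the values, the log2 change had a median of 0.00 and an SD of 0.13 over probes, and 95% of probes lay between -0.27 and 0.28. No probe differed by more than 1 on the log2 scale, and 14 differed by more than 0.5 in either direction. The extremes were 0.75 and -0.65. The 95% confidence interval of the log2 change reached, at the median over probes, 0.19 to either side of the estimate, and 0.47 among the 119 probes of highest mean intensity. Because most probes lie near the floor, which was not subtracted, a change in transcript abundance would appear smaller on this scale than it is. With normexp background correction 5 probes differed by more than 1 on the log2 scale and 161 by more than 0.5, while the 95% confidence interval reached 0.68 to either side at the median, and limma called 0 probes.

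**Figure D3:**
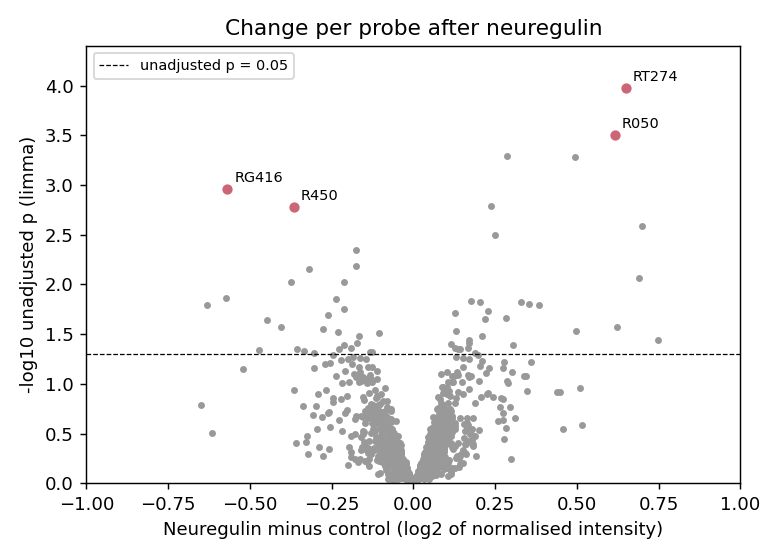
Each point is 1 of 1185 probes, with the neuregulin minus control difference in normalised log2 intensity on the x axis and -log10 of the unadjusted limma p on the y axis. The dashed line marks an unadjusted p of 0.05, passed by 59 probes, and the 4 labelled probes are those of smallest p in each direction.

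The probes of smallest p in each direction were RT274 and R050, with higher means after neuregulin, and RG416 and R450, with lower means. Probe RT274 had a normalised log2 intensity of 12.48 ± 0.14 (SD, n = 6) in control cells and 13.12 ± 0.27 (SD, n = 6) with neuregulin. Its difference was 0.65 with a standard error of 0.12, a ratio of 1.57 (limma adjusted p = 0.125). After quantile normalisation every neuregulin array lay above every control array. As deposited intensity over the array median, the groups overlapped. Controls 3 and 4, at 3.57 and 3.44, lay above neuregulin arrays 1, 2 and 5, at 2.34, 1.45 and 3.29. The RT274 difference was 0.83 with median centring (limma adjusted p = 0.999) and 0.55 without normalisation (limma adjusted p = 0.902). With normexp background correction it was 0.92 (limma adjusted p = 0.669). Complete separation of the groups after quantile normalisation was seen for 3 probes, all higher with neuregulin, where chance gives 0.216% of probes or 2.56 of them. Probe R050 averaged 11.56 ± 0.11 (SD, n = 6) in controls and 12.17 ± 0.31 (SD, n = 6) with neuregulin, a difference of 0.62 with a standard error of 0.13 (limma adjusted p = 0.156). It passed 2 times the array median on 1 of the 12 arrays, and its difference was 1.25 with normexp background correction (limma adjusted p = 0.401) and 0.34 without normalisation (limma adjusted p = 0.902).

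Probe RG416 was bright on all 12 arrays. It averaged 15.62 ± 0.20 (SD, n = 6) in controls and 15.05 ± 0.30 (SD, n = 6) with neuregulin, a difference of -0.57 with a standard error of 0.13 (limma adjusted p = 0.259). Quantile normalisation gave controls 1, 3 and 4 and neuregulin array 4 the same value, 15.55. The SD and standard error of this probe therefore rest on ranks. With median centring its difference was -0.34 (limma adjusted p = 0.999). Probe R450, which passed 2 times the array median on 1 array, averaged 12.04 ± 0.17 (SD, n = 6) and 11.67 ± 0.16 (SD, n = 6), a difference of -0.37 with a standard error of 0.09 (limma adjusted p = 0.281). Its difference was -0.76 with normexp background correction (limma adjusted p = 0.993) and -0.62 without normalisation (limma adjusted p = 0.902). For both probes, all 6 neuregulin arrays lay below the control mean. For RT274 and R050, all 6 lay above it. The probes were picked for small p on these same arrays, so this is no separate support.

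**Figure D4:**
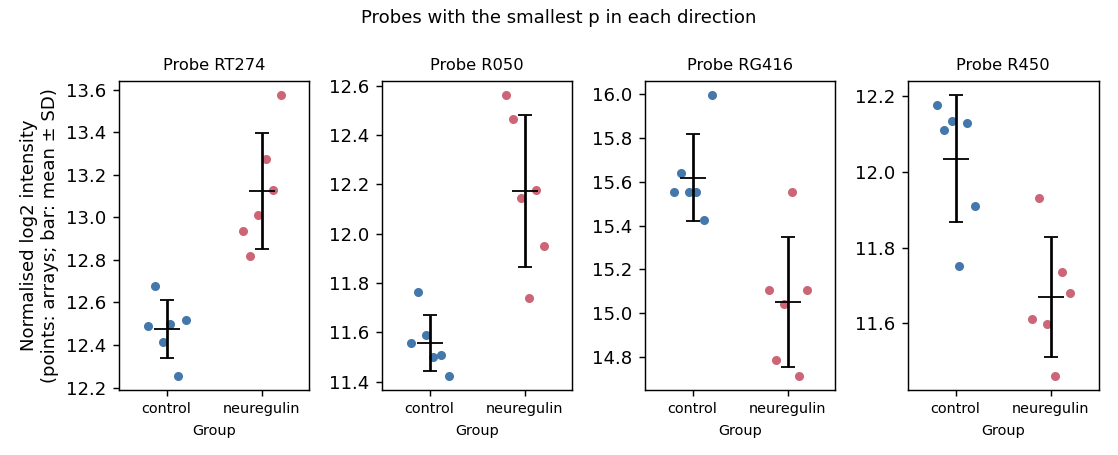
Normalised log2 intensity of the 4 probes of smallest p in each direction, with 1 point per array and the mean ± SD of 6 arrays per group as bars; each panel has its own y range, which does not start at 0. Of the 4, only RT274, at 12.48 in controls and 13.12 with neuregulin, shows no overlap between the groups, and none of the 4 passed the adjusted threshold.

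Taking the signal classes into account also gave no call. With the class as a block in the model, limma called 0 probes (smallest adjusted p = 0.122). Among the 4 bright arrays alone 0 probes were called (limma, smallest adjusted p = 0.387), and 107 reached an unadjusted p under 0.05. Among the 5 arrays of the low floor class 0 were called (limma, smallest adjusted p = 0.986), and 26 reached it. Chance gives 59.3 on average, and neither the 107 nor the 26 was set against relabellings of so few arrays. The high floor class holds 1 neuregulin array and was not fitted on its own. The high floor arrays, normalised on their own, gave differences of 0.12 for RT274, 0.33 for R050, -0.76 for RG416 and -0.09 for R450 between 1 neuregulin array and 2 controls, with no test. The difference for RT274 was 0.94 in the bright class and 0.79 in the low floor class. For R050 it was 0.66 in both. For RG416 it was -0.35 and -0.60, and for R450 it was -0.69 and -0.30.

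Changes in the weight of single arrays moved this count. With weights estimated per array, RT274 passed (limma adjusted p = 0.0122). These weights were 1.92 to 3.39 on the bright arrays and 0.37 to 1.23 on the others, so the call rests mostly on the bright arrays. Without neuregulin array 4, R050 and RG416 passed (limma adjusted p = 0.0393 and 0.0495).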

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

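The 4 array measures and the 4 probes checked here in each group were chosen after the data were examined. In the group of 6 controls, array 6 stood apart for probe RG416, at a normalised log2 intensity of 16.00 against 15.43 to 15.64 on the other 5 arrays. The gap was 0.626 of the group's range, just past the 0.625 that Dixon's criterion allows for 6 values. It was the only 1 of 16 such checks to be past it, and chance gives about 1 in 20. Quantile normalisation gave control arrays 1, 3 and 4 the same value for this probe, so the gap is between rank positions. As deposited intensity over the array median, control 6 was at 17.3, inside the 8.30 to 61.6 of the other 5 controls.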

How the results depend on the processing

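The count of 0 probes past an adjusted p under 0.05 was the same in 27 of 29 alternatives, among them the exact permutation test, whose smallest possible p left little room for a call. Other alternatives had little room too. The threshold of 0.10 reuses the main fit, whose smallest limma adjusted p was 0.125. The smallest limma adjusted p was 0.902 without normalisation and 0.999 with median centring, and the fits of single classes used few arrays. The 27 are therefore not separate pieces of support. The count became 1 with array weights, and it ranged from 0 to 2 when single arrays were left out, reaching 2 only without neuregulin array 4. The probe called with array weights was RT274, and those called without neuregulin array 4 were R050 and RG416. Over all alternatives that tested them, the log2 difference was 0.54 to 0.94 for RT274 and 0.34 to 1.25 for R050. It was -0.65 to -0.34 for RG416 and -0.76 to -0.27 for R450. None turned direction, but these probes were chosen on arrays that the alternatives reuse, so this is no separate support. The adjusted p of RT274 ran from 0.0122 to 0.999 over the alternatives. The number of probes at an unadjusted p under 0.05 was 59 in the main model. It was 0 for the deposited values without normalisation and 16 with median centring. It was 93 with the replicate block, 102 with array weights and 92 with the signal class as a block. In the filter to probes above 2 times the array median it was 12 of 179. The bright arrays alone gave 107 and the low floor arrays alone 26. Leaving out single arrays gave 46 to 85. Fewer probes were tested in the filter to 179; the cause of the other changes was not tested. Without normalisation the median log2 difference over all probes was -0.26, against 0.00 in the main model. Same-numbered arrays had deviations that correlated at -0.21 for number 1, 0.10 for number 4 and 0.55 to 0.73 for the others. Number 1 was not over 0.1, and the main model stayed without the number as a block, as fixed beforehand. Except for number 1, same-numbered arrays were of the same signal class. A batch or culture shared by number therefore stays open, and the main model ignores any such pairing. Of the neuregulin arrays, 1 and 4 correlated best with controls 2 and 3, and the other 4 with the control of their own number. The replicate block called 0 probes. The alternatives for missing values and for the gene lists were not run, because no value is missing and no probe has a gene name. The 866 probes that never passed 2 times the array median may be limited by signal over background, which was not measured.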

Other observations

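Of the tests in this part, those of the count past the adjusted threshold and of independent noise were chosen after the result had been seen; the others were written down before, though the test of signal over the floor was judged more strictly after its values were seen.

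Other splits of the arrays were set against treatment. Of 100 splits of the 12 arrays into 6 and 6, the real one included, 100 gave at least the 0 probes past the adjusted threshold that treatment gave, which any split must, so this comparison decides nothing. Of the other splits, 3 gave any call. The highest, with 39, set control arrays 1 to 4 and neuregulin arrays 1 and 2 against the rest, and the next gave 1. For probes at an unadjusted p under 0.05, 36 of the 100 splits gave at least the real 59, and the highest other gave 300, so chance is not excluded. These splits mix the signal classes and the array numbers, and no relabelling within numbers was run. With the class as a block and arrays relabelled only within classes, 12 of 100 relabellings, drawn from 180 with the real one included, gave at least the real 92. The median of the others was 50 and the highest 134, so chance is not excluded there either. With array weights, where RT274 was called, 13 of the 100 splits gave at least 1 call and the highest other gave 52, so chance is not excluded for that call.

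Control arrays 1 and 2 and neuregulin array 2 had lower rank correlations with the other 9 arrays (median rho 0.676) than those 9 had with each other (0.875), a gap of 0.199. Little signal over the floor is a candidate explanation that was not settled. Among the 119 probes of highest mean intensity the gap was 0.0448, but the correlation among the 9 arrays fell by more (from 0.875 to 0.760) than that of the 3 arrays with them rose (from 0.676 to 0.715). Noise independent in each array would leave deviations from the group means uncorrelated between arrays of different groups. They correlated at 0.55 for control 2 with neuregulin 2 and at 0.27 for control 1 with neuregulin 2 (the median of the 3 pairs). These values argue against independent noise as the only source, for these arrays. For control 1 with control 2 the value was -0.08, where centring alone gives -0.20. Control 2 correlated higher, at 0.71, with neuregulin 1 from outside the 3. A part played by independent noise is not excluded. A shared hybridisation, exposure or culture also stays open, because the labels name none of these. No biological explanation was tested.

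A hypothesis was that neuregulin changed the same probes in the bright and in the low floor arrays, which share no array. The log2 differences in the 2 classes correlated at r = 0.165 across 1185 probes, and 650 probes (54.9%) had the same sign in both. Of the 60 ways to relabel the arrays within the classes, 14 gave a correlation as high, with a highest of 0.326 (exact permutation test, one-sided, p = 0.233, adjusted p = 0.283 over 2 sets of probes). Among the 179 probes that passed the filter on the array median r was 0.161. Of the 60 relabellings, 17 were as high (exact permutation test, one-sided, p = 0.283, adjusted p = 0.283). The relabellings leave open whether there is a common change. The 4 probes named above kept their direction in both classes, but these arrays are part of those they were chosen on.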
